A study of Mus musculus with 5 samples.

How the data were processed

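Expression was measured in 5 cultures of mouse epiblast stem cells of the E3 line, pluripotent cells derived from the post-implantation epiblast, with 1 array per condition. Per the labels' protocols, the cells grew on inactivated CF1 mouse embryonic fibroblasts in medium with knockout serum replacement and 5 ng/ml FGF2, and at semiconfluence the medium was replaced for 12 h by one without supplements, which is called untreated here. The other 4 cultures received the same medium with 1 µM PD0325901, an inhibitor of the kinase MEK (called PD), with 3 µM CHIR99021, an inhibitor of the kinase GSK3 (CH), with 1000 U/ml of leukemia inhibitory factor (LIF), or with all of these agents at the same doses (PCL). The untreated medium thus also lacked FGF2. RNA was isolated on spin columns, and 400 ng of it was amplified by in vitro transcription and labelled with Cy3, per the labels' protocols.

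The authors deposited a scanner table for each array, which per the file headers holds a mean bead intensity, the standard error over the beads of a probe, and a detection p-value for each of 25697 probes. BeadStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited intensity was on a linear scale, and its lowest values lay between 67.6 and 71.4, so no background had been subtracted. The deposited detection p-value had steps of 1 in 798, as the share of that many negative control probes. The authors also deposited a table of processed intensity values, rounded to whole numbers on a linear scale, with no value below 9 and with 51.1% of the untreated entries listed as null. Its medians over listed probes were 100 for the untreated, PD, CH and LIF arrays and 99.5 for PCL, and its ranks matched those of the scanner intensities with Spearman's rho of 1.00 after rounding. The method of scaling and background subtraction behind that table stays unknown, and it was used as an alternative only.

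The scanner intensities were background-corrected and normalized together with neqc of limma 3.58.1 in R 4.3.3. This applies a normal-exponential convolution with negative control parameters inferred from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. The offset pulls differences of dim probes towards 0. A probe was called detected on an array at a detection p under 0.01, and a gene entered a comparison when its probe was detected on at least 1 of the 2 arrays compared. Gene lists and correlations used the 8138 genes detected on at least 1 of the 5 arrays. A list member detected only on the array where it is high enters through that value, which favours a difference in that direction. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

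Probes were named through a platform annotation table: 23978 probes had 1 gene symbol, 0 had several and 1719 had none. Entrez identifiers of 23962 probes matched a RefSeq gene table for the assembly GRCm38.p6, and 0 symbols changed by that match. The probe sequences were not used here, and no coordinates are given. For the 4777 of 16593 genes with several probes, the probe with the highest mean level represented the gene. For genes given by their difference from untreated, other detected probes are stated beside the gene where they gave a clearly different value, and all other values rest on the brightest probe alone. Genomic span, used in a check of short against long genes, came from the same RefSeq table for 8132 of the 8138 detected genes. It includes introns and is only a proxy for transcript length.

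With 1 array per condition there is no replicate check of any difference, and no p-value across genes was computed. Values are log2 differences between 2 arrays with the bead standard error, which was propagated from the 2 arrays to the log2 scale and covers measurement within an array, not the spread between cultures. The number of arrays limits the precision. Differences were counted past 2-fold in measured values, which for probes not well above background on 1 array can exceed their bound, and the counts at the bounds are given beside. Where the probe was not well above background on 1 of the 2 arrays, only a bound is given as "at least N-fold": the brighter array's level against the higher of the dimmer array's lowest level among detected probes and the probe's own level there. No fold is given where neither array detected the probe.

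Before the data were examined, 24 gene lists and a rule for the genes to be named were fixed. The rule took, for each of the 4 comparisons with untreated, the 10 genes most higher and the 10 most lower past 2-fold with model names left out, up to 4 detected members of each list with the largest absolute difference, a fixed panel of pathway, pluripotency and reference genes, and the 5 largest departures in each direction of PCL from the sum of the single treatments. The lists covered targets of ERK, Wnt, STAT3, Nodal, BMP, Hippo and FoxO signalling, naive, core and epiblast pluripotency, primitive streak, neural ectoderm, trophoblast, endoderm, feeder fibroblasts, epithelial and mesenchymal state, DNA methylation, the cell cycle, p53, the integrated stress response, heat shock, cholesterol synthesis, glycolysis and housekeeping. Each list's median over detected members was placed among 10000 random lists of the same size matched on level in 10 bins. The resulting percentile describes these arrays only, and the median's interval came from 1000 bootstrap draws over members. Some fixed names, such as the gene for Brachyury, were not analysed here.

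Comparisons with the same untreated array share its error. Agreement of a single treatment with PCL was therefore read from differences that share no array, such as PD minus untreated with PCL minus CH. The normalization was tested on simulated arrays in which 200 of 25697 probes differed between PCL and untreated, under 2 noise models. The changed probes were drawn from those detected on every array at intermediate untreated levels. Recovery of changes in dim probes was therefore not tested. With background noise drawn independently for each probe and array, 100% of log2 changes of -2, 98% of -1.5, 100% of 1.5 and 100% of 2 were recovered, 22 unchanged probes passed 2-fold, and 27 probes passed it between a pair of unchanged arrays. A simulation with bead error only, added after that result was seen, recovered 98%, 98%, 100% and 100% of the same changes, with 0 such unchanged probes and 1 in the unchanged pair. Neither holds the spread between cultures. In simulated lists of 20 genes over 8138 genes, 5% of 200 unshifted lists and 100% of lists shifted by 0.5 fell outside the central 95% of random lists. Unshifted random lists give about 5% by construction. Smaller shifts, like many of the list medians given below, were not simulated. The alternatives were 12 fixed beforehand (background correction, offset, normalization, detection filter, probe choice, control array and the authors' values) and 3 added after the data were seen.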

Results

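Gene expression was profiled on 5 bead arrays in mouse epiblast stem cells that had been kept for 12 h in medium without supplements (untreated) or with PD, CH, LIF or their combination PCL. Each condition had 1 array, so no difference below has a replicate check, and each ± is the bead standard error on the log2 scale, which covers measurement within the arrays only. Between 10389 probes on the PCL array and 10898 on the LIF array were detected, out of 25697. The median bead standard error of detected probes was 4.13% to 4.39% of the signal. Median raw intensity lay between 90.0 and 96.1, close to the median of 80.6 to 85.8 at the level of the negative controls, so dim genes carry little signal over background. Counts past 2-fold therefore depend on the background correction and on the offset added before the log: with PD they were 8 higher and 6 lower without background correction, 15 and 10 with an offset of 50 and 210 and 195 with an offset of 1.

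The arrays differed from each other to unequal extents. CH and PCL were the closest pair, with 64 genes at least 2-fold apart among 7578 compared, and LIF and PCL the farthest, with 301 among 7712. On the LIF array 106 genes lay at least 2-fold below all 4 other arrays, against 0 on the untreated, CH and PCL arrays and 1 on the PD array. Of the reference genes, Gapdh differed from untreated by -0.06 ± 0.04 with PD, -0.22 ± 0.04 with CH, 0.08 ± 0.04 with LIF, where its other probe stood at 0.36, and -0.08 ± 0.04 with PCL. Actb differed by 0.02 ± 0.06 with PD, 0.07 ± 0.06 with CH, 0.46 ± 0.06 with LIF and 0.01 ± 0.06 with PCL, with its other probes at -0.89 to 0.08, -0.37 to 0.44, -0.84 to 0.38 and -0.21 to 0.05. The sign of the Gapdh value with PD, CH and PCL turned under other settings, at up to 0.21, 0.05 and 0.22. That of Actb turned on every treated array, at down to -0.40, -0.09, -0.13 and -0.10 with PD, CH, LIF and PCL. The housekeeping list of 10 detected genes had medians of -0.07, 0.03, 0.12 and 0.02 with PD, CH, LIF and PCL.

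**Figure D1:**
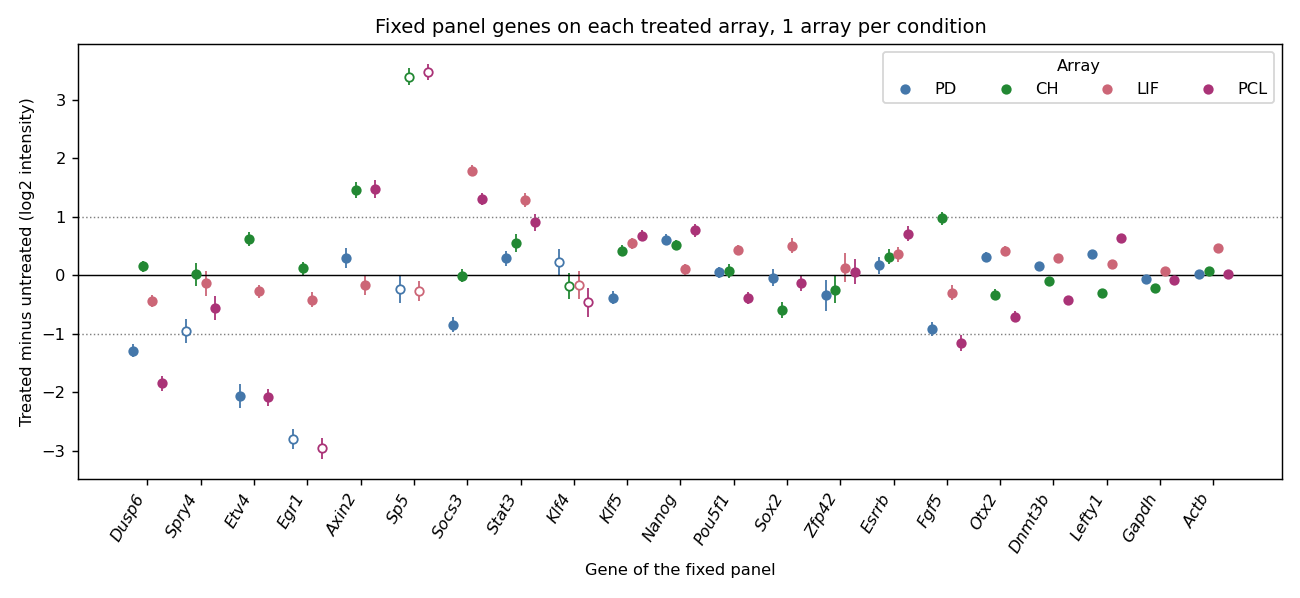
Log2 difference from the untreated array (vertical axis) for the fixed panel genes detected on at least 1 array (horizontal axis), with 1 point per treated array. Bars are bead standard errors, open points mark a probe not well above background on at least 1 of the 2 arrays and dotted lines mark 2-fold, with Etv4 standing at -2.07 with PD and -2.09 with PCL, Axin2 at 1.46 with CH and 1.48 with PCL, and Socs3 at 1.79 with LIF and 1.30 with PCL.

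The comparison of PD with untreated asked which transcripts differ when MEK, the kinase that activates ERK, is inhibited. Of 20 detected targets and feedback regulators of ERK signalling, 18 stood below 0 on the PD array. Egr1, an immediate early transcription factor, was at least 6.57-fold lower and was not well above background with PD. The ETS factor Etv4 stood at -2.07 ± 0.20, and the MAP kinase phosphatases Dusp4 and Dusp6 at -1.72 ± 0.13 and -1.29 ± 0.11, with the other probes of these phosphatases at -0.92 and -0.56. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was at least 1.79-fold lower. Of the members of this list, 5 were at least 2-fold lower (Egr1, Etv4, Dusp4, Dusp6 and Dusp14), 0 were at least 2-fold higher and 15 lay between. The list's median of -0.60 was below all 10000 random lists matched on level, and was -0.23 with no detection filter.

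Over all genes, 38 stood at least 2-fold higher and 35 at least 2-fold lower in measured values with PD among 7761 compared, and 32 and 28 with probes not well above background on 1 array set at their bound. The highest were Foxd4, a forkhead factor, which was at least 4.56-fold higher, and Lox, a collagen crosslinking enzyme, at 2.12 ± 0.11. They were followed by the secreted proteins Igfbp5 at 1.49 ± 0.08, Timp3 at 1.48 ± 0.15 and Thbs1 at 1.36 ± 0.20, the stromal glycoprotein Cd248 at 1.48 ± 0.14, the homeobox factor Irx3 at 1.46 ± 0.16, Chrna4 at 1.37 ± 0.14, the transglutaminase Tgm2 at 1.37 ± 0.13 and Ap2b1 at 1.33 ± 0.09. The other probes of Cd248, at 0.37, of Chrna4, at 1.02, and of Ap2b1, at 0.12 to 0.90, gave less. Besides the ERK targets, the lowest were Psors1c2 at -1.78 ± 0.24, the protease inhibitor Spink1 at -1.53 ± 0.09 and the interferon-induced Bst2 at -1.38 ± 0.28, with Sema7a at least 2.87-fold and the chemokine Ccl11 at least 1.84-fold lower. The brighter probe of Pdyn was at least 2.89-fold lower and its other probe stood at 0.20.

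Among pluripotency genes with PD, Nanog stood at 0.61 ± 0.09 and the naive state factor Klf2 at 0.83 ± 0.15. The naive list members Klf5 and Zfp42 stood lower, at -0.38 ± 0.11 and -0.35 ± 0.26, and Esrrb stood at 0.17 ± 0.14. Over the 16 detected members of that list, 6 stood above 0 and 10 below. The epiblast factor Otx2 stood higher, at 0.31 ± 0.08. The epiblast marker Fgf5 stood at -0.91 ± 0.12, Utf1 at -1.12 ± 0.12, the Nodal co-receptor Tdgf1 at -1.09 ± 0.20 and the methylation cofactor Dnmt3l at -1.17 ± 0.11. The brightest probe of Pou5f1 stood at 0.05 ± 0.09, with values down to -0.28 in other settings, and its other probe at -0.60. List medians were -0.14 for naive pluripotency (16 detected, percentile 8.26), 0.01 for core pluripotency (16 detected, 2 at least 2-fold lower, percentile 55.1), -0.05 for epiblast stem cell genes (25 detected, 2 at least 2-fold lower, percentile 27.0) and 0.11 for DNA methylation enzymes (6 detected, 1 at least 2-fold lower, percentile 79.2). The means of the core and DNA methylation lists were -0.11 and -0.13, opposite in sign to their medians. Socs3, a STAT3 target, stood at -0.85 ± 0.13 with PD, while the STAT3 target list of 24 detected genes had a median of 0.00.

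Some fibroblast and matrix genes stood higher with PD. The list of feeder fibroblast markers, the other cell type in these cultures, had 28 detected members, of which 3 were at least 2-fold higher (Lox, Timp3 and Fbln2, a matrix fibulin, at 1.11 ± 0.10, with its other probes at 0.34 to 0.49) and 1 at least 2-fold lower (Mgp, matrix Gla protein, at -1.03 ± 0.20). Its median was 0.24 (percentile 99.9), with 21 members above 0 and 7 below. Medians above the central 95% of random lists were also found for the lists of epithelial and mesenchymal genes (0.24, with the repressors Zeb1 at 0.69 ± 0.16 and Zeb2 at 0.65 ± 0.18), Hippo and cytoskeleton targets (0.21, with Ccn2 at 0.59 ± 0.06), neural ectoderm genes (0.52 over 8 detected, with Irx3 and the retinoic acid binding protein Crabp2 at 0.88 ± 0.17) and Nodal targets (0.26). The mean of the Nodal list was -0.05, opposite in sign to its median. Bootstrap intervals held 0 for the medians of Nodal targets (-0.48 to 0.31) and neural ectoderm genes (-0.44 to 0.88). Medians below that central 95% were found for primitive streak genes (-0.26, with 9 of 16 members detected on neither array), Wnt targets (-0.25), BMP targets (-0.40 over 6 detected), primitive and visceral endoderm genes (-0.23) and the integrated stress response (-0.16). With members detected on 1 of the 2 arrays set at their bound, the Wnt median was -0.14 and the BMP median -0.24. Bootstrap intervals also held 0 for Wnt targets (-0.44 to 0.12), BMP targets (-0.49 to 0.23), endoderm genes (-0.41 to 0.30) and the integrated stress response (-0.21 to 0.01). Genes of long genomic span were higher than genes of short span on this array, with a median of 0.15 in the longest and -0.14 in the shortest of 10 groups of equal size by span.

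Under median scaling the split with PD was 60 higher and 19 lower genes, on a scale where the median of all compared genes was 0.07. The neural ectoderm median with PD turned to -0.06 at a detection p under 0.05 and to -0.03 with no detection filter, and the Nodal list turned to -0.14 against the mean of arrays without PD. The Wnt list turned to 0.02 with the authors' values and to 0.00 over members detected on both arrays.

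The comparison of CH with untreated asked which transcripts differ when GSK3, a kinase that promotes degradation of beta-catenin, is inhibited. On the CH array, 14 of 16 detected genes of the primitive streak, the embryonic site of mesoderm and endoderm formation, and 11 of 16 detected Wnt targets stood above 0. Of these streak genes, 10 were detected on 1 of the 2 arrays only, and 34 are on the array in all. Of the Wnt targets, 5 were detected on 1 of the 2 arrays only. Members detected only where they are high enter through that value, so the detection filter itself favours these counts above 0. The activin antagonist Fst stood at 3.46 ± 0.12, the growth factor Fgf8 at 2.66 ± 0.12, the organizer homeobox gene Gsc at 2.38 ± 0.12 and Wnt8a at 2.34 ± 0.13, with its other probes at 1.88 to 2.33. The Wnt-induced transcription factor Sp5 was at least 7.35-fold higher and the homeobox gene Gbx2 at least 4.42-fold higher, both not well above background in untreated cells. Axin2, a negative feedback regulator of Wnt signalling, stood at 1.46 ± 0.14.

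Of the primitive streak list, 6 members stood at least 2-fold higher in measured values, 4 of which (Fgf8, Gsc, Sp5 and Eomes) also at their bound, and 0 at least 2-fold lower. Its median of 0.77 lay above all 10000 random lists, and was 0.52 with members detected on 1 of the 2 arrays set at their bound. It was 0.10 with no detection filter and 1.47 over members detected on both arrays. Of those members, the T-box factor Eomes was at least 2.27-fold higher, while Mixl1 was bounded at 1.75-fold, with its other probe at 0.94, and Wnt3 at 1.61-fold. Of the 16 detected Wnt targets, 4 were at least 2-fold higher (Sp5, Wnt8a, Axin2 and the receptor Tnfrsf19 at 1.95 ± 0.14) and 1 at least 2-fold lower (Fgf4 at -1.33 ± 0.21), with a median of 0.27 at percentile 99.7. The bootstrap interval of that median ran from -0.17 to 0.88, and it was 0.15 without background correction, 0.10 with no detection filter and 0.46 over members detected on both arrays. Nodal, the TGF-beta family ligand, stood at 1.33 ± 0.16, and the median of the Nodal target list was 0.10 (percentile 86.2).

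Over all genes, 44 stood at least 2-fold higher and 30 at least 2-fold lower in measured values with CH among 7699 compared, and 32 and 18 with such probes at their bound. The 10 most higher also held Rtl8c, at least 4.16-fold higher, the co-receptor Tgfbr3 at 1.98 ± 0.18 and the ectonucleotidase Nt5e at 1.76 ± 0.17, with other probes at 1.39 and 0.94. The 10 most lower were Mgp (at least 2.89-fold), Slc35d3 (at least 2.17-fold), Bcl11a (at least 2.35-fold), Ctsf (at least 1.84-fold), Slc6a13 (at least 1.60-fold), the GSK3-binding protein Frat2 at -1.38 ± 0.19, Fgf4, Ramp3 at -1.30 ± 0.18, Uchl1 at -1.28 ± 0.19 and the linker histone H1f10 at -1.18 ± 0.13. The other probes of Ramp3, at -0.94 to -0.65, and of H1f10, at -0.99, did not reach 2-fold. Mgp stood lower than untreated on every treated array, and these differences share the untreated array. Under median scaling the split was 63 higher and 20 lower genes, on a scale where the median of all compared genes was 0.09. Without background correction no gene was at least 2-fold lower, against 11 higher.

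Among the pluripotency genes with CH, Nanog stood at 0.52 ± 0.08, Klf2 at 0.88 ± 0.15, Esrrb at 0.32 ± 0.13 and Fgf5 at 0.97 ± 0.10. Sox2 stood at -0.59 ± 0.14, with its other probe at 0.12, and the Wnt pathway repressor Tcf7l1 at -0.66 ± 0.06. The core pluripotency list had a median of -0.17 (percentile 0.87, 12 of 16 members below 0), the naive list -0.09 (with a mean of 0.06, opposite in sign) and the epiblast stem cell list -0.10 (percentile 8.60), with 4 of its 25 detected members at least 2-fold higher at their value or bound (Fst, Fgf8, Eomes and Nodal) and Pou3f1 at least 2-fold lower. The mean of that list was 0.29, opposite in sign to its median. The neural ectoderm list had a median of 0.55 over 8 detected members at percentile 99.99, with Gbx2, Irx3 at 0.95 ± 0.18 and Sox21 at 0.64 ± 0.14, and turned to -0.02 with no detection filter. The bootstrap interval of that median with CH ran from -0.21 to 0.80.

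Other lists with CH outside the central 95% of random lists were Hippo and cytoskeleton targets at 0.18 (bootstrap interval -0.06 to 0.33), which turned to -0.06 against the mean of arrays without CH, and glycogen synthase kinase, insulin and FoxO targets at -0.18 (percentile 2.2), with Txnip at -0.68 ± 0.08 and Cited2 at 0.90 ± 0.16. The latter list had 20 genes on the array for 19 fixed names, as 1 name covered the separate genes Eif4ebp1 and Eif4ebp2. The feeder list had a median of -0.08 (percentile 13.3), with 1 of 28 members at least 2-fold lower. ERK targets had a median of 0.15 (percentile 96.6), with Etv4 at 0.62 ± 0.11 and Dusp4 at -0.58 ± 0.10, whose other probe stood at -0.13. Across settings, Etv4 lay between 0.45 and 1.40 and Dusp4 between -0.65 and 0.05 with CH. The epithelial and mesenchymal list had a median of -0.10 (percentile 13.0), with the tight junction protein Cldn3 at -1.07 ± 0.15.

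The comparison of LIF with untreated asked which transcripts differ when the LIF receptor and its effector STAT3 are stimulated. Of 24 detected STAT3 targets, 18 stood above 0 on the LIF array. Socs3, the feedback inhibitor of this pathway, stood at 1.79 ± 0.10 and Stat3 itself at 1.29 ± 0.12, with its other probes at 0.92 or more. Of these targets, Socs3 and Stat3 were at least 2-fold higher, 0 were at least 2-fold lower and 22 lay between, among them the survival factor Mcl1 at 0.73 ± 0.07 and the coactivator Bcl3, which was at least 1.71-fold higher. The list's median was 0.35 (percentile 99.99), with values from 0.10 with no detection filter to 0.46 under median scaling, and the medians of the same list with PD and CH were 0.00 and 0.13.

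Over all genes, 12 stood at least 2-fold higher and 219 at least 2-fold lower in measured values with LIF among 7796 compared, and 8 and 209 with probes not well above background on 1 array at their bound. The other genes among the 10 most higher were Ahcy, an enzyme of the methionine cycle, at 1.87 ± 0.16, the guanylate-binding protein Gbp2 at 1.20 ± 0.09, the DNA damage kinase Atm at 1.11 ± 0.22, the repressor Bach1 at 1.09 ± 0.14, the uridine phosphorylase Upp1 at 1.07 ± 0.07 and the tRNA synthetase Mars1 at 1.04 ± 0.08, with Zfp825 at least 1.66-fold and Six5 at least 1.35-fold higher. The other probes of Atm and Mars1 stood at 0.40 and 0.27, and those of Gbp2 at 0.99 and of Upp1 at 0.70 to 0.87. The 10 most lower were the histone genes H2ac21 at -2.83 ± 0.11 and H2ac11 at -2.56 ± 0.12, Bola2 at -2.52 ± 0.11, the complex I subunit Ndufa3 at -2.50 ± 0.09, Spink1 at -2.44 ± 0.08, Dpm3 at -2.33 ± 0.11, the mitochondrial ribosomal proteins Mrpl52 at -2.32 ± 0.09 and Mrps21 at -2.19 ± 0.15, the cytochrome c oxidase subunit Cox7a1 at -2.25 ± 0.13 and Romo1 at -2.22 ± 0.21.

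The lower genes on the LIF array were mostly of short genomic span. Their median span was 3857 bp, against 21096.5 bp for all detected genes with a span, and 66 of the 219 were left without the 1627 genes of shortest span, a comparison chosen after the data were seen. The median difference from untreated with LIF was -0.30 in the shortest and 0.14 in the longest of 10 groups of genes by span. On the PCL array, which also received LIF, the corresponding medians were -0.05 and 0.02. Median scaling moved the median of all compared genes with LIF to 0.19, and gave 48 higher and 170 lower genes on that scale. The number of lower genes was 6.26 times that with PD, 8.95 times under median scaling and 7.26 times under cyclic loess. That ratio was 2.04 with an offset of 1, 2.12 with the authors' values and 21.5 without background correction.

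Detected members of the naive and core pluripotency lists differed by less than 2-fold with LIF, with the exception of Dppa5a at -1.11 ± 0.08 in the naive list. Klf5 stood at 0.54 ± 0.10, Esrrb at 0.35 ± 0.13, Sox2 at 0.50 ± 0.13, Pou5f1 at 0.43 ± 0.09 and Nanog at 0.10 ± 0.10, which lay between -0.28 and 0.16 across settings. The other probes of Sox2 and Pou5f1 stood lower, at 0.09 and 0.26. List medians were 0.11 for naive pluripotency (percentile 77.4, with a mean of -0.02), 0.19 for core pluripotency (percentile 88.3) and -0.11 for epiblast stem cell genes (percentile 3.38). The streak gene Fgf8 stood at -1.40 ± 0.15 and Wnt8a at -2.05 ± 0.21, with its other probes at -1.84 to -1.07, while the streak list had a median of 0.01, with a mean of -0.12, and the Wnt list of -0.13 (percentile 8.61). Metabolic lists were higher: glycolysis and hypoxia genes had a median of 0.39, above all 10000 random lists, with 20 of 23 members above 0 and Slc2a1, a glucose transporter, at 0.82 ± 0.06 and the hexokinase Hk2 at 0.74 ± 0.07. Cholesterol synthesis genes had a median of 0.27 (percentile 98.8), with Hmgcs1 at 0.71 ± 0.05, and cell cycle genes 0.25 (percentile 98.7), with the replication factor Mcm6 at 0.87 ± 0.09 and its other probes at -0.10 to 0.51. None of the members of these 3 lists reached 2-fold. The bootstrap interval of the cell cycle median with LIF ran from -0.01 to 0.44. On the PCL array, which also received LIF, these lists were not higher. Their medians there were 0.02 for glycolysis and hypoxia (percentile 61.2), -0.02 for cholesterol synthesis (percentile 37.1) and -0.10 for cell cycle genes (percentile 1.84). The shift between short and long genes on the LIF array, given above, may enter the medians with LIF too, which was not tested. The feeder list had a median of 0.04 with LIF (percentile 46.3), with Lgals1 at -1.67 ± 0.11 and Mgp at -1.33 ± 0.17.

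**Figure D2:**
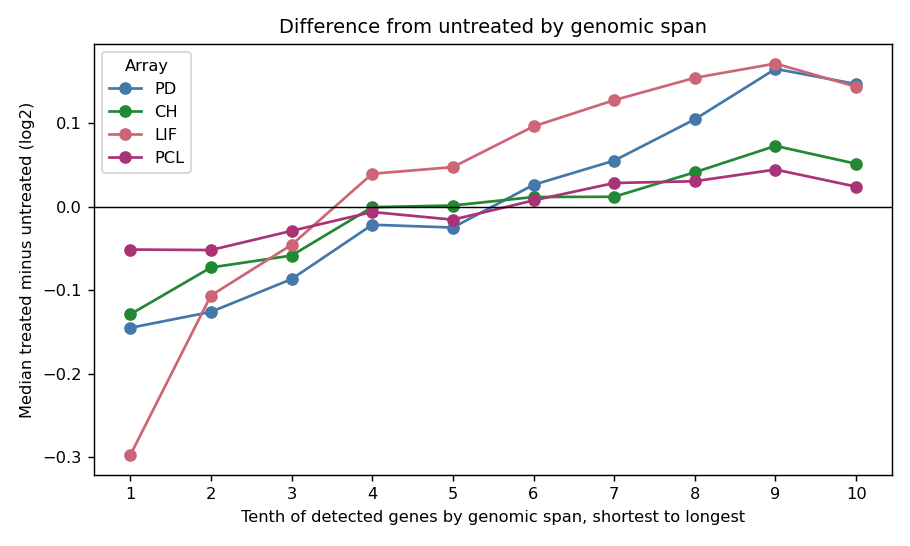
Median log2 difference from the untreated array (vertical axis) for detected genes in 10 groups of equal size by genomic span, from shortest to longest (horizontal axis), with 1 line per treated array. The LIF line runs from -0.30 to 0.14, the PD line from -0.14 to 0.15 and the PCL line from -0.05 to 0.02.

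The comparison of PCL with untreated asked which transcripts differ when all of the agents are given together. On the PCL array, 17 of 20 detected ERK targets stood below 0 and 11 of 16 streak genes above 0, the Wnt targets Sp5, Axin2, Wnt8a and Tnfrsf19 and the STAT3 feedback gene Socs3 were at least 2-fold higher, and the pluripotency factors Klf2, Nanog and Esrrb stood above untreated. Egr1 was at least 6.14-fold lower, Etv4 stood at -2.09 ± 0.14, Dusp4 at -2.08 ± 0.13 and Dusp6 at -1.85 ± 0.12, with the other probes of these phosphatases at -1.19 and -1.15. Sp5 was at least 7.77-fold and Gbx2 at least 12.9-fold higher, and Fgf8 stood at 2.66 ± 0.13 and Axin2 at 1.48 ± 0.15. Socs3 stood at 1.30 ± 0.10 and Stat3 at 0.90 ± 0.14, with its other probes at 0.36 to 0.96.

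Of the naive pluripotency list, 16 members were detected, of which 3 were at least 2-fold higher (Gbx2, Klf2 at 2.17 ± 0.13 and Fbxo15 at 1.26 ± 0.13) and 1 at least 2-fold lower (Fgf4 at -1.83 ± 0.19). Its median was 0.10 at percentile 88.6. Nanog stood at 0.76 ± 0.12, Esrrb at 0.71 ± 0.12, Klf5 at 0.67 ± 0.10 and Zfp42 at 0.06 ± 0.22. Klf4 was not well above background on the untreated and PCL arrays. Epiblast stem cell genes had a median of -0.19 at percentile 0.11, with 3 of 25 members at least 2-fold lower (Pou3f1 at -1.61 ± 0.12, Car4 at -1.41 ± 0.13 and Fgf5 at -1.16 ± 0.13), Tcf15 at least 1.87-fold lower and 2 at least 2-fold higher (Fst and Fgf8). The epiblast list did not move as a whole, with 11 members above 0 and 14 below and a mean of -0.02. The bootstrap interval of its median ran from -0.57 to 0.24. With members detected on 1 of the 2 arrays set at their bound, the median was -0.13. Otx2 stood at -0.71 ± 0.10. Core pluripotency genes had a median of -0.17 at percentile 0.36, with Utf1 at -1.77 ± 0.12, Dppa4 also at least 2-fold lower and Pou5f1 at -0.39 ± 0.10. The bootstrap interval of the core median ran from -0.43 to 0.02, with 6 members above 0 and 9 below. Dnmt3b stood at -0.42 ± 0.06 with its other probe at -1.18, and Dnmt3l at -1.12 ± 0.11.

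Over all genes, 54 stood at least 2-fold higher and 52 at least 2-fold lower in measured values with PCL among 7652 compared, and 48 and 35 with such probes at their bound. The 10 most higher also held Ap3b2, at least 4-fold higher, Rtl8c, at least 4.02-fold higher, Irx3 at 2.44 ± 0.16, the Wnt receptor Fzd10 at 2.14 ± 0.15 (other probes 1.79 to 2.13), Fst at 2.10 ± 0.15 and Tnfrsf19 at 2.05 ± 0.16. The 10 most lower also held the apolipoprotein Apoa1, at least 2.44-fold lower, Slc35d3, at least 2.10-fold lower, Frat2 at -1.87 ± 0.17 and Spink1 at -1.66 ± 0.09. Further members of fixed lists past 2-fold included the transcription factor Tfap2c at 1.82 ± 0.11, the coactivator Cited2 at 1.89 ± 0.16 and the stress factor Ddit3 at 1.02 ± 0.12. The other probes of Tfap2c stood at 1.13 to 1.61 and that of Ddit3 at 0.50.

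Of the lists that represent the pathways, ERK targets had a median of -0.55 with PCL, below all 10000 random lists, with 5 of 20 members at least 2-fold lower, and of -0.25 with no detection filter. STAT3 targets had a median of 0.12 (percentile 97.8, 3 of 24 at least 2-fold higher), against 0.13 with CH and 0.35 with LIF. The STAT3 median with PCL therefore does not separate an effect of LIF from one of CH. Its 3 members past 2-fold were Socs3, Gbx2 and Gadd45g. Socs3 stood at -0.01 with CH, while Gbx2 was at least 4.42-fold higher there. Gadd45g stood at 1.18 with PCL and -0.40 with LIF. Wnt targets had a median of 0.14 (percentile 93.1, 9 of 16 above 0, 4 at least 2-fold higher and 1 lower, and -0.00 with no detection filter) and primitive streak genes 0.42 (above all random lists, 2 of 16 at least 2-fold higher, 7 detected on 1 of the 2 arrays, 0.33 at the bounds and 0.06 with no filter). The neural ectoderm median was 0.30 at percentile 98.0, and turned to -0.02 at a detection p under 0.05 and to -0.07 with no filter. Bootstrap intervals with PCL ran from -0.08 to 0.82 for the streak median and from -0.12 to 2.44 for the neural ectoderm median. Cell cycle genes had a median of -0.10 (percentile 1.84, 20 of 28 members below 0), with the inhibitor Cdkn1a at 0.84 ± 0.07 (other probes 0.45 to 1.00) and Ccnd1 at -0.47 ± 0.07, and the integrated stress response -0.14 (percentile 0.49). BMP targets had a median of -0.39 at percentile 2.65 over 6 detected members, 3 of them detected on 1 of the 2 arrays, and of -0.19 at the bounds. The feeder list had a median of 0.05 (percentile 83.1), with Lox at 1.39 ± 0.11, Timp3 at 1.49 ± 0.15 and the collagen Col1a1 at 1.12 ± 0.17 past 2-fold and Mgp at least 2.80-fold lower.

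**Figure D3:**
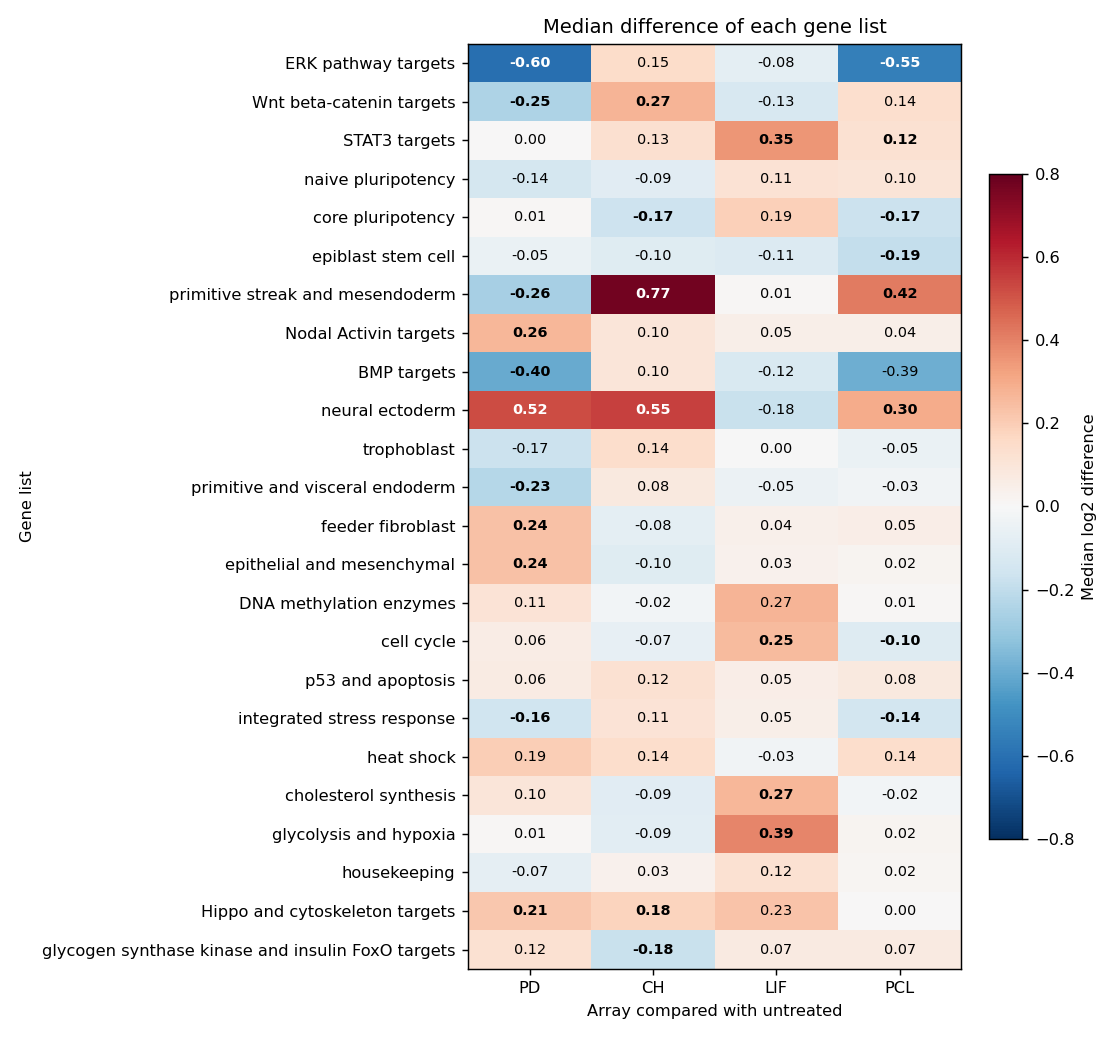
Median log2 difference from the untreated array of the detected members of each of the 24 gene lists (rows) on the PD, CH, LIF and PCL arrays (columns), with colour and printed number giving the median. Bold numbers lie outside the central 95% of 10000 random lists, which holds for ERK targets at -0.60 with PD and -0.55 with PCL and for primitive streak genes at 0.77 with CH and 0.42 with PCL.

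Whether a single treatment and PCL shared effects was read from differences that share no array. Of the 44 genes at least 2-fold higher with CH, 42 were higher on the PCL than on the PD array, and 20 of these by at least 2-fold, where lists drawn independently would share 0.278. In PCL minus LIF, 35 of the 44 were higher and 19 by at least 2-fold, against 1.31 for independent lists. Of the 30 genes at least 2-fold lower with CH, 25 were lower in PCL minus PD and 20 in PCL minus LIF, with 7 and 8 by at least 2-fold, against 0.149 and 0.241. Fst stood at 2.58, Fgf8 at 2.86, Wnt8a at 2.28 and Gsc at 1.51 in PCL minus PD. Over all genes tested in both, 48.4% were higher in PCL minus PD, 45.5% in PCL minus LIF and 50.7% in PCL minus CH.

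Of the 35 genes at least 2-fold lower with PD, 26 were lower on the PCL than on the CH array and 11 by at least 2-fold, against 0.148 for independent lists, with Etv4 at -2.71 and Dusp4 and Dusp6 also past 2-fold. In PCL minus LIF, 23 of the 35 were lower and 9 by at least 2-fold, against 0.284, where 54.5% of all genes were lower. Of the 38 genes at least 2-fold higher with PD, 25 were higher in PCL minus CH and 6 by at least 2-fold, against 0.113 for independent lists, with Lox at 1.43, Irx3 at 1.48 and Timp3 at 1.29 past it, while Igfbp5 stood at 0.58. In PCL minus LIF, 22 of the 38 were higher and 5 by at least 2-fold, against 1.13.

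Socs3 and Stat3, higher with LIF, stood at 2.15 and 0.61 in PCL minus PD, and at 1.31 and 0.36 in PCL minus CH. Gbp2, at 1.20 with LIF, stood at -0.30 and 0.08 in the same differences. Of the 12 genes at least 2-fold higher with LIF, 6 were higher in PCL minus PD and 7 in PCL minus CH, with 1 by at least 2-fold in each, against 0.0540 and 0.0245 for independent lists. Of the 219 lower genes, 100 were lower in PCL minus PD and 92 in PCL minus CH, with 2 by at least 2-fold in each, against 1.32 and 0.984 for independent lists. Across 8138 genes, which are not independent replicates, Pearson's r between such differences was 0.219 and 0.138 for CH, 0.157 and -0.0902 for PD and -0.172 and 0.00176 for LIF, 6 correlations in all. These pairs share no array with each other, yet a trend common to several arrays still enters them.

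**Figure D4:**
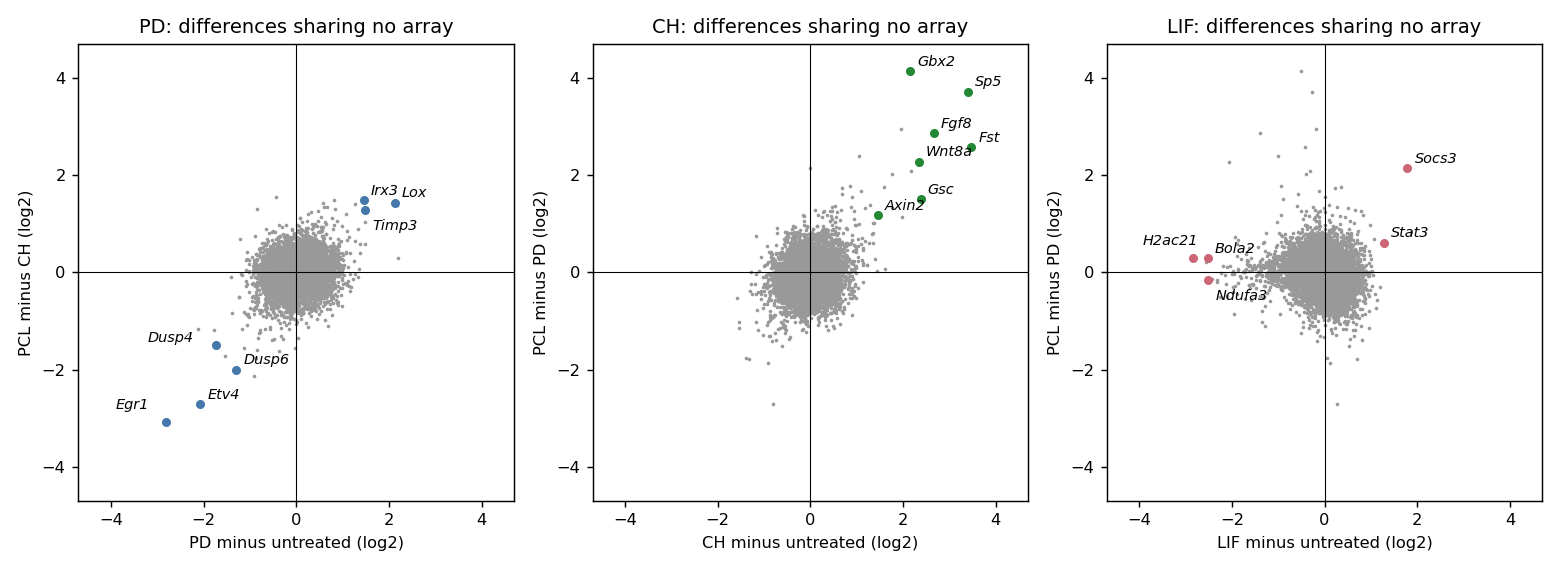
Each point is a gene detected on at least 1 array, with its log2 difference from untreated under a single treatment (horizontal axis) and its log2 difference of PCL from another single treatment (vertical axis), for PD, CH and LIF from left to right. Coloured points are named genes at their measured values, such as Etv4 at -2.07 and -2.71 in the PD panel, Fst at 3.46 and 2.58 in the CH panel and Socs3 at 1.79 and 2.15 in the LIF panel.

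Differences taken from the shared untreated array are correlated through it. Pearson's r across genes ranged from 0.323 for LIF with PCL to 0.580 for CH with PCL over the 6 pairs, where simulated unchanged arrays with bead error alone gave 0.514 to 0.525. The covariances were 0.0416 to 0.0742 against 0.0139 to 0.0140 in the simulation. Part of that excess may come from the shared untreated array, since its culture-to-culture spread was not simulated.

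The PCL difference was also compared with the sum of the single differences. The untreated array enters this departure 2 times. The SD of the departure over all genes was 0.72, and its spread between cultures was not measured. Of the pathway genes, Axin2 stood at -0.10 ± 0.32, Dusp6 at -0.27 ± 0.21, Etv4 at -0.36 ± 0.29, Klf5 at 0.10 ± 0.20 and Esrrb at -0.13 ± 0.26. The other probe of Dusp6, at -0.56, 0.56, 0.12 and -1.15 with PD, CH, LIF and PCL, departs further below the sum. Socs3 stood at 0.37 ± 0.22. Stat3 stood at -1.22 ± 0.27, Otx2 at -1.09 ± 0.18, Fgf5 at -0.91 ± 0.24 and Pou5f1 at -0.94 ± 0.20, and the reference gene Actb at -0.55 ± 0.11. These departures rest on the brightest probe of each gene. The other probe of Pou5f1, at -0.60, -0.21, 0.26 and -0.42 with PD, CH, LIF and PCL, gives no such departure. Over 8138 genes, 715 departed upward and 572 downward by at least 1 log2 unit. With the other arrays normalized again without the LIF array, against the sum of PD and CH alone, 89 departed upward and 125 downward among 8005 genes, a comparison chosen after the data were seen, and median scaling gave 386 upward and 1348 downward. Under median scaling the median of all compared genes was 0.07 with PD, 0.09 with CH, 0.19 with LIF and -0.03 with PCL. That raises the sum of the single differences against PCL and favours downward departures.

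The largest departures were held by genes that stood out on the single-treatment arrays. The 5 most upward were H2ac21 at 3.50 ± 0.19, Bola2 at 2.89 ± 0.21, H2ac11 at 2.88 ± 0.21, Smim11 at 2.76 ± 0.26 and the metallothionein Mt2 at 2.69 ± 0.58, with PCL differences between -0.84 for Mt2 and 0.05 for H2ac11 and LIF differences between -2.83 for H2ac21 and -1.89 for Smim11. The 5 most downward were Tenm4 at -2.58 ± 0.40, Atm at -2.47 ± 0.45, Bach1 at -2.43 ± 0.30, Cacna1h at -2.43 ± 0.39 and the sorting receptor Sorl1 at -2.40 ± 0.34, each above untreated on all 3 single-treatment arrays. Against the sum of PD and CH alone, the same upward genes stood between 0.32 for H2ac11 and 0.87 for Smim11, and the same downward genes between -1.78 for Tenm4 and -1.34 for Bach1. The median departure was 0.55 in the shortest and -0.34 in the longest of the 10 groups of genes by span. Of the 24 lists, 1 had a median departure below the central 95% of random lists, the Hippo and cytoskeleton targets at -0.49 (percentile 1.74), and 0 had one above it.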

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

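The counts in this part were planned. Probes that the annotation table leaves without a gene name were outside all comparisons above, and some differed by at least 2-fold from the untreated control array. At least 2-fold higher were 4 of 636 such probes with PD, 7 of 624 with CH, where the largest difference was 2.48, 1 of 639 with LIF and 4 of 627 with PCL. At least 2-fold lower were 4, 0, 13 and 4 of the same probes with PD, CH, LIF and PCL. Which transcripts they measure was not analysed here, and no explanation was tested.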

How the results depend on the processing

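Chosen after the data were seen were the settings without the LIF array, without the 1627 shortest genes and without the feeder list; the other settings were planned. No paired analysis was possible because each condition had 1 array, so the groups share fewer than 2 replicate numbers. Of the genes named as most higher or most lower, 0 changed sign in any setting. They were chosen as the largest differences on the same arrays, which favours a stable sign. Past 2-fold in every setting were 3 of 10 higher and 3 of 10 lower genes with PD, 8 and 0 with CH, 3 and 10 with LIF, and 9 and 6 with PCL. Over all named genes, 34 of 438 differences turned sign in at least 1 setting, and of their values in single settings 1434 moved by more than the bead standard error and 3941 did not. Of the counts, 76 stayed within 1.5 times and 58 moved further. A detection p under 0.05 or no detection filter left the 8 counts of higher and lower genes as they were. Signal over background limits dim genes, whose differences shrink as the offset grows.

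Without background correction, counts of higher and lower genes were 8 and 6 with PD, 11 and 0 with CH, 4 and 129 with LIF and 15 and 9 with PCL, and 249 genes departed upward and 114 downward from the sum. The mean r of differences sharing no array was 0.0023 for PD and -0.1198 for LIF, against 0.0336 and -0.0852 in the chosen setting, and the ERK list median was -0.2776 with PD and -0.2954 with PCL. With normexp and an offset of 50, counts were 15 and 9 with PD, 16 and 4 with CH and 25 and 13 with PCL, 6 genes were higher with LIF, 320 departed upward and 187 downward, and the mean r for LIF was -0.1096. With neqc and an offset of 50, they were 15 and 10 with PD, 17 and 5 with CH and 28 and 17 with PCL, 6 were higher with LIF, 365 departed upward and 218 downward, and the mean r for LIF was -0.107. With an offset of 1, they were 210 and 195 with PD, 180 and 202 with CH, 173 and 398 with LIF and 183 and 230 with PCL, 980 departed downward, and the mean r for LIF was -0.0575. A larger offset shrinks log2 differences by its construction.

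Median scaling gave 60 higher and 19 lower genes with PD, 48 higher with LIF, 386 upward and 1348 downward departures, and a STAT3 list median of 0.4584 with LIF. Under that scaling the median of all compared genes lay above 0 with PD, CH and LIF, which enters these values. The authors' values gave counts of 177 and 169 with PD, 140 and 161 with CH, 113 and 359 with LIF and 172 and 173 with PCL, a mean r of 0.1397 for CH, and a STAT3 list median of 0.4465 with LIF. That median was smaller in other settings, at 0.1443 without background correction, 0.1988 with normexp and 0.2215 with neqc at an offset of 50, 0.1049 with no detection filter and 0.2313 against the mean of arrays without LIF. The Wnt list median with CH was 0.1476 without background correction, 0.1039 with no detection filter, 0.4553 over genes detected on all arrays compared and 0.4532 against the mean of arrays without CH, against 0.2697 in the chosen setting. With no detection filter, the ERK list median was -0.2254 with PD and -0.2548 with PCL, over more dim members. Over genes detected on all arrays compared, 23 were lower with PD, 26 higher and 14 lower with CH and 28 lower with PCL, by construction fewer, and the mean r for LIF was -0.1121. Against the mean of the arrays without the agent, 22 were lower with PD. Without the LIF array, 89 genes departed upward and 125 downward, where the other arrays were normalized again, the sum held fewer arrays and 8005 genes entered. Without the 1627 shortest genes, 66 were lower with LIF.

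Among list medians outside the central 95% of random lists, those that turned sign were the Wnt list with PD at 0.0171 with the authors' values and 0.0049 over genes detected on all arrays, and the neural ectoderm list at -0.0585 with PD and -0.0221 with PCL at a detection p under 0.05, and at -0.032 with PD, -0.0223 with CH and -0.0664 with PCL with no filter. Against the mean of the arrays without the agent, the Nodal list with PD turned to -0.1365 and the Hippo list with CH to -0.0593. Medians within the central 95% turned sign in several settings too, such as the Wnt list with PCL, at -0.0007 with no filter against 0.1369. Except where stated, the cause was not tested.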

Other observations

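The gene families in this part, the tests of recurrence of the LIF difference in PCL and of the families as the whole cause, and all tests on the feeder list were chosen after the values they rest on were seen, and the feeder tests were also revised after a first form was run; the other tests were written beforehand.

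On the LIF array, several gene families stood lower. Of 33 detected NADH dehydrogenase subunits, which form complex I of the respiratory chain, 17 were at least 2-fold lower, with a family median of -1.08. Lower by at least 2-fold were also 4 of 6 ubiquinol cytochrome c reductase genes (median -1.27), 7 of 13 cytochrome c oxidase genes (-1.10), 7 of 15 ATP synthase genes (-0.82) and 18 of 39 core and linker histones (-0.95). Medians were smaller in size for ribosomal proteins, at -0.44 for 57 cytosolic and -0.40 for 71 mitochondrial ones, each with 11 at least 2-fold lower, for 20 Sm and Lsm proteins of the splicing machinery at -0.51, with 4 lower, and for 18 mitochondrial import proteins at -0.27, with 5 lower. On the PD, CH and PCL arrays the medians of these 9 families lay between -0.25 and 0.07, and 1 histone gene on each of these arrays was at least 2-fold lower. Under median scaling, cyclic loess and the authors' values, the LIF medians of these families kept their sign, between -1.40 and -0.22.

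The fixed lists not described above stayed within the central 95% of random lists on every array. The 20 detected p53 and apoptosis genes had medians of 0.06, 0.12, 0.05 and 0.08 with PD, CH, LIF and PCL, with the p53 target Zmat3 at 0.94 ± 0.08 with PD. The 9 detected heat shock genes had medians of 0.19, 0.14, -0.03 and 0.14, with the mitochondrial chaperonin Hspe1 at -1.04 ± 0.13 with LIF, and the 9 detected trophoblast genes -0.17, 0.14, -0.00 and -0.05.

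Over the 219 genes lower on the LIF array the median of PCL minus the mean of PD and CH was 0.034 (quartiles -0.0874 to 0.149), which argues against a LIF effect that recurs in PCL, while an effect of LIF alone that PD or CH blocks stays untested. Quantile normalization as the cause is argued against by the ratio to the lower genes with PD, 6.26 in the chosen setting, 8.95 under median scaling and 7.265 under cyclic loess, though 2.12 with the authors' values, whose scaling is unknown, and 2.04 with an offset of 1. Loss of signal from short genes may contribute, since among genes not 2-fold different the longest of 10 groups by span stood 0.39 above the shortest with LIF, yet the gap was 0.285 with PD, which had 35 lower genes, and 0.173 and 0.0604 with CH and PCL. A change of the families cannot be the whole cause, since 135 of the 219 genes lie outside them, while for the 84 family genes it stays open, as the median of short genes outside the families, -0.164, lay between the bounds set beforehand. Family genes stood at -0.73 among the 1627 shortest genes. In the longer 5 of 10 groups, 22 family genes stood at -0.24 (quartiles -0.53 to 0.06), against 0.14 (-0.07 to 0.33) for 4044 other genes. This gap does not decide between span and the families. The families were chosen after their values were seen, span was not matched within these groups, and it is only a proxy for transcript length.

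For the feeder list genes higher with PD, a larger share of feeder RNA as the whole cause of the members past 2-fold could not be decided. The median of all 28 members, 0.236 (interval 0.0929 to 0.548), lay below 2-fold. Yet such a share would raise members alike only where the stem cells do not express them, and that was not checked. As a source of the smaller shift, a larger share of feeder RNA could not be decided either: 75% of members stood higher, the 7 lower ones are 25% (exact interval 10.7% to 44.9%), and the 5 most abundant had a median of 0.107. In its first form, with a bound of 25% lower members, that test counted against feeder RNA, at the bound itself. A PD effect that recurs in PCL also stays open, at a median of PCL minus CH of 0.117 (-0.0267 to 0.336) over the list, and of 0.243 over all 38 genes higher with PD in the first form of the test. Of the 28 members, 1 is in another list, and how many the stem cells also express was not analysed here.

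For the 715 genes higher in PCL than the sum of the single treatments, neither technical explanation could be decided, and no biological explanation was tested. PCL was the brightest of the 5 arrays in 25.874% of these genes and untreated in 64.2%, but a high untreated level, counted 2 times in the departure, is what selects them, so error of the untreated array stays open. A LIF difference of -0.5 or less was found in 74.406% of them, which the selection also favours, so the low signal of short genes on the LIF array stays open as well.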
